A study of Mus musculus with 7 samples.

How the data were processed

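Total RNA of 7 mouse samples was labelled with Cy3, 250 ng each, and hybridised to single-colour Agilent 8x60K expression arrays. The cultured samples were adult mouse cardiac mesenchymal progenitors (CMPs), grown in medium with 10% serum and 40 ng/ml basic fibroblast growth factor. They came from atrial and from ventricular tissue, either of living animals or of tissue held for 24 h at 4 °C after death, with 1 array for each of these 4 sources. Commercial adult heart RNA (1 array) and fetal heart RNA of embryonic day 16.5 (1 wild-type array and 1 array of a line carrying a Myh6-EGFP transgene) served as positive controls per the labels. Samples were grouped from the labels as postmortem CMPs (2 arrays), living CMPs (2 arrays), adult heart (1 array) and fetal heart (2 arrays).

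The authors deposited a scanner table for each array, whose intensity columns hold linear spot brightness: the raw mean signal, the median local background, and a processed signal that was background-subtracted with spatial detrending and then multiplicatively detrended, per the file headers. The program was Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 9.5.3 per the submitters' processing notes. The same deposited tables carry flags for spots well above background, saturated spots and outliers. The authors also deposited a series table of log2 values, 1 column per array, with steps beyond Feature Extraction not given in the sources used here. Against the scanner values, each of its columns equalled the log2 processed signal minus a constant for 100% of probes within 0.001, so its direction is known and its genes were not centred across arrays. Its column medians were -4.25, -4.17, -4.21 and -4.13 for postmortem atrial, postmortem ventricular, living atrial and living ventricular CMPs, -3.60 for adult heart, and -4.03 and -3.87 for the fetal hearts.

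Each array held 59305 non-control spots for 55681 probes. Spots of 1 probe were averaged (432 probes had more than 1 spot), and 11 probes with an outlier flag on at least 1 array were left out. Between 46.5% and 52.5% of probes were well above background on an array, and no spot was saturated. The number of arrays limits the precision of every comparison. The log2 processed signal minus each array's 75th percentile was the working value. A gene, taken as a gene name of the array's design, was represented by its probe of highest mean over all arrays. Of 34792 gene names, 11173 had more than 1 probe, 20190 matched an accession of the RefSeq gene table, and 2099 of the current symbols differ from the array's, which are the ones printed. Probe positions are those of the deposited tables, on mouse build mm9.

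Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) in 1 fit of all 7 arrays with terms for living CMPs, postmortem CMPs, adult heart, fetal heart and CMP chamber, which left 2 residual degrees of freedom. A gene was tested where its probe was well above background on every array of at least 1 side. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and all tests were two-sided. The dependence of the postmortem difference on chamber was tested with an interaction term, which left 1 residual degree of freedom, from the fetal pair. Where a probe was not well above background on any array of a group, the group has only a bound. The brighter group's mean was then set against the mean, over the dim arrays, of the higher of the dim signal and the lowest signal well above background on that array, and is given as "at least N-fold".

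A set of 29 gene lists was fixed before the data were examined, together with the comparisons, the alternatives and the rule for named genes. The lists cover cardiac muscle and its regulators, stromal, vascular, blood, epicardial, neural, fat and bone cell types, sex-linked genes, and growth, stress and immune responses. A list with at least 3 tested members was tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The limma test fry was run beside it, once for a shift in 1 direction and once for differences in either direction. All were adjusted over the lists of a comparison. For 1 direction the smallest adjusted p of fry was 0.171 for postmortem against living CMPs and 0.439 for the chambers. Against fetal heart the sarcomere list had an adjusted p = 0.00512 in it. No call of camera at the preset correlation held with an estimated correlation in any of the 5 comparisons. With 2 residual degrees of freedom that setting could hardly be passed by any list. Against fetal heart even the sarcomere list, with all 24 members called lower and a median of -10.79, had an adjusted p = 0.344 in it. A failure there therefore does not tell shifted lists from unshifted ones. Genes named are, for each comparison, the 6 largest called differences in each direction, with arrays of the sides not overlapping (within each chamber between CMPs) and at least 2-fold apart. Where fewer than 6 passed, genes at least 2-fold apart in the same direction in both pairs filled the places and are given as values. Names that are probe, clone, predicted-gene or accession names were passed over. Up to 4 members of largest difference from each list were added, as were Myh6, Nkx2-5, Gata4, Thy1, Col1a1, Pecam1, Ptprc and Mki67. Some genes that this rule names are not reported here.

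The gene test was tested on simulated data with the fitted spread, with 50 genes changed at each of 2-, 4-, 8- and 16-fold. For postmortem against living CMPs it recovered 2%, 56%, 72% and 96% of them, with 8 false calls among 121. For ventricular against atrial CMPs the shares were 0%, 40%, 78% and 94%. For CMPs against fetal heart they were 4%, 58%, 92% and 94%. Against adult heart they were 0%, 34%, 52% and 86%, and for adult against fetal heart 0%, 16%, 52% and 74%. In this order the simulated heart comparisons gave 133, 89 and 75 calls, while the data gave 9555, 9878 and 7610. Of the calls in the data, 7123, 8502 and 6831 were at least 2-fold, so some lay below that size. The simulated shares hold for few changed genes and do not say what share of changes the heart comparisons recovered. The interaction test recovered 4%, 32%, 48% and 90% when the spread was drawn as its own fit estimated it, and 0% at every size when it was drawn as in the fit of all arrays.

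Alternatives were normexp background correction on the raw signals (offset 50), quantile normalization, the deposited series table, no filter on dim probes, a filter that asks for every array of the comparison, the mean of a gene's probes, eBayes without a trend or robust, an added 2-fold minimum, the 4 CMP arrays alone, no term for the other CMP factor, and leaving out each array of a pair. All arrays lay on 1 slide with 1 scan, so no slide or scan could be used as a block. The CMP arrays filled row 1 of the slide and the heart arrays row 2, and postmortem CMPs lay at positions 1 and 2 with living CMPs at positions 3 and 4. Position and group can therefore not be told apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome sequence was used here.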

Results

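Transcript levels were compared between cardiac mesenchymal progenitors (CMPs), adherent stromal cells cultured from adult mouse heart tissue, and heart RNA. Postmortem CMPs came from tissue stored for 24 h at 4 °C and living CMPs from fresh tissue, each with 1 atrial and 1 ventricular array. The 3 heart arrays were 1 of adult and 2 of fetal (embryonic day 16.5) RNA. The postmortem atrial array stood apart from the other CMPs. It differed at least 2-fold from the other 3 CMP arrays at 4689 to 5298 of 24885 genes well above background on at least 1 array, while those 3 differed from one another at 2416 to 2712. The fetal hearts differed from each other at 3674 genes. Arrays of a group differ in chamber or, for fetal heart, in genotype, and nothing in the labels says that they are repeated cultures or separate animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation set a list's genes against other genes as if nearly independent. Their size does not measure the spread between samples. For postmortem against living CMPs the estimated correlation was 0.04 for inflammatory, 0.33 for cell cycle and 0.69 for immediate early genes. All values below are log2 differences ± SE from limma unless another measure is named.

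The central comparison asked whether CMPs of stored postmortem tissue differ from CMPs of living tissue. Gpc3, a cell surface proteoglycan of embryonic growth control, and Chrdl2, a secreted antagonist of bone morphogenetic proteins, were well above background on both living arrays and on neither postmortem array. Gpc3 was at least 15.0-fold lower in postmortem CMPs (adjusted p = 0.0335) and Chrdl2 at least 14.2-fold lower (adjusted p = 0.0399), though with normexp, which shrinks dim signals, they fell by 2.33 and 2.41. Emb, a membrane glycoprotein that chaperones monocarboxylate transporters, fell by 2.32 ± 0.21 (adjusted p = 0.0476, 2 arrays against 2). Tmem204, a claudin-like membrane protein, was the 1 gene that rose, by 3.88 ± 0.29 (adjusted p = 0.0335), and was higher in both chambers. The probes lie at positions 49625740 to 49625799 of chromosome X for Gpc3, 107183146 to 107183205 of chromosome 7 for Chrdl2, 118062731 to 118062790 of chromosome 13 for Emb and 25195330 to 25195389 of chromosome 17 for Tmem204 (mm9). Altogether 20 of 19011 genes tested passed, 1 higher and 19 lower in postmortem CMPs, and 2084 had an unadjusted p under 0.05. The split was 9 and 44 with normexp and 16 and 46 with no filter on dim probes. The main probes of Wdr92 (-2.94 ± 0.18) and Pip5k1a (-2.70 ± 0.20) and the transcript named BB713741 (-2.24 ± 0.18) were also called lower. The other Wdr92 probe differed by -0.10, and the other 2 Pip5k1a probes by -0.43 to 0.09. The remaining 13 lower calls, from -2.90 to -2.10, carried probe, clone or accession names, and 12 of the 19 probes called lower shared a stretch of at least 20 bases with another of them.

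Other large differences between postmortem and living CMPs did not pass the test. By group means, Dlk1, an imprinted inhibitor of adipocyte differentiation, was at least 23.1-fold higher in postmortem CMPs (adjusted p = 0.266), and Cytl1, a cytokine-like secreted protein, at least 8.68-fold (adjusted p = 0.0748). Both bounds rest mostly on the postmortem atrial array, where log2 signals were 3.55 for Dlk1 and 0.37 for Cytl1. On the postmortem ventricular array they were -3.05 and -2.70. The other Dlk1 probe differed by 3.77. Penk, the enkephalin precursor, dim on 1 living array, had a difference of 5.07 ± 1.00 and Galntl2, a glycosyltransferase also dim on 1 living array, one of 4.78 ± 0.81, while Akr1c19 was at least 6.52-fold higher. Among stromal surface markers, Nt5e (CD73) had a difference of -2.54 ± 0.27 (adjusted p = 0.0651) and Alcam (CD166) one of 2.34 ± 0.33 (adjusted p = 0.132). Thy1 (CD90) differed by 0.63 ± 0.31 and Col1a1 by -0.39 ± 0.19. The cardiac transcription factors Gata4 (-0.98 ± 0.64) and Nkx2-5 (-0.81 ± 0.74) and the endothelial marker Pecam1 (-0.45 ± 0.49) had adjusted p-values from 0.644 to 0.801, and all 3 changed sign without the postmortem or the living atrial array. No gene passed in limma without a trend (1993 genes at an unadjusted p under 0.05), with the 4 CMP arrays alone (2207), without a chamber term (1601), or without either fetal heart array (2221 and 2218). Leaving out a CMP array left the spread to the fetal pair alone and gave 398 (without postmortem atrial), 1695 (postmortem ventricular), 468 (living atrial) and 1551 (living ventricular) calls, which held all 20. Of these 224, 838, 141 and 515 were higher in postmortem CMPs, so the share of lower calls varied with the array left out.

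Proliferation genes stood higher in postmortem CMPs. Of 22 tested cell cycle genes, 21 were higher, with a median of 0.73 (camera adjusted p = 5.17e-15, adjusted p = 0.827 with an estimated correlation). The replicative helicase subunit Mcm5 (1.02 ± 0.26), the survivin gene Birc5 (1.00 ± 0.17), Top2a (0.97 ± 0.25), Cdc20 (0.97 ± 0.16) and Mki67 (0.93 ± 0.19) were among them. None passed over all genes tested, while 17 passed in limma adjusted over the list alone, the same number as had an unadjusted p under 0.05. In fry the list had an adjusted p = 0.171 for 1 direction and an adjusted p = 0.0472 for either direction. The list stood higher in both chambers, with medians of 0.87 in the atrial and 0.62 in the ventricular pair.

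Inflammatory cytokine and chemokine genes stood lower in postmortem CMPs. All 16 tested members were lower, with a median of -2.94, or -2.26 with 1 gene at its bound (camera adjusted p = 5.78e-15, adjusted p = 0.567 with an estimated correlation). The acute phase gene Saa3 (-7.47 ± 1.85), the neutrophil chemoattractants Cxcl5 (-6.13 ± 1.75) and Cxcl1 (-3.93 ± 0.83) and the siderophore-binding Lcn2 (-4.42 ± 0.82) differed most. Saa3 was well above background on 1 of the 2 postmortem arrays. None passed over all genes tested and 14 passed adjusted over the list alone (14 at an unadjusted p under 0.05). Fry gave the list an adjusted p = 0.171 for 1 direction and an adjusted p = 0.0472 for either direction. The list median was -3.70 in the atrial and -1.90 in the ventricular pair. In the same order Saa3 differed by -11.81 and -3.13 and Cxcl1 by -5.78 and -2.07. Markers of macrophages and leukocytes had a median of -0.33 (adjusted p = 0.064) and were lower for 8 of 11 members.

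Hypoxia-responsive genes stood lower in postmortem CMPs at 15 of 19 members, with a median of -0.76 (camera adjusted p = 3.84e-05, adjusted p = 0.827 with an estimated correlation). The mTOR inhibitor Ddit4 (-1.68 ± 0.30), the collagen prolyl hydroxylase subunit P4ha2 (-1.45 ± 0.24), the mitophagy receptor Bnip3 (-1.42 ± 0.31) and the pyruvate dehydrogenase kinase Pdk1 (-1.32 ± 0.28) led the list. None passed over all genes, and 7 passed adjusted over the list alone (7 at an unadjusted p under 0.05). The list did not pass fry, with an adjusted p = 0.563 for 1 direction and an adjusted p = 0.0598 for either direction. In the atrial pair the median was -0.37 and in the ventricular pair -0.78, and without the postmortem or the living ventricular array the list no longer passed (adjusted p = 0.0661 and 0.111).

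A further 5 lists passed camera close to its threshold. Extracellular matrix genes were lower for 19 of 27 members (median -0.16, adjusted p = 0.0498), TGF-beta responsive genes for 13 of 17 (median -0.45, adjusted p = 0.0434), led by Comp (-2.94 ± 1.18, but -5.62 in the atrial and -0.26 in the ventricular pair), and Schwann and neural genes for 4 of 6 (median -0.78, adjusted p = 0.0434), led by Fabp7 (-4.39 ± 0.74, dim on 1 postmortem array). Interferon-response genes were lower for 16 of 19 members (median -0.39, adjusted p = 0.0498), and immediate early genes were higher for 13 of 15 (median 0.57, adjusted p = 0.0498), with Dusp1 at 1.61 ± 0.48 and Fos at 1.18 ± 1.04. For these 5 lists the adjusted p = 0.827 to 0.873 with an estimated correlation, and in limma 1 member, of the Schwann and neural list, passed adjusted over the list alone, while 2 to 5 members had an unadjusted p under 0.05. Without the postmortem or the living atrial array the interferon median was 0.37 and the immediate early median -0.65 or -0.66, both passing in the opposite direction (adjusted p = 0.0108 to 0.0283), and the TGF-beta (-0.15) and Schwann and neural lists (-0.46) did not pass. The Schwann and neural median was 0.13 with the stricter filter, and the matrix list passed in 1 of 13 other settings. Lists that did not pass included mesenchymal stromal surface markers (median 0.02, adjusted p = 0.682), cardiac transcription factors (median 0.17, adjusted p = 0.96), endothelial genes (median -0.90, adjusted p = 0.186), p53 and apoptosis genes (median 0.21, adjusted p = 0.064) and heat, cold and unfolded protein stress genes (median 0.14, adjusted p = 0.656).

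**Figure D1:**
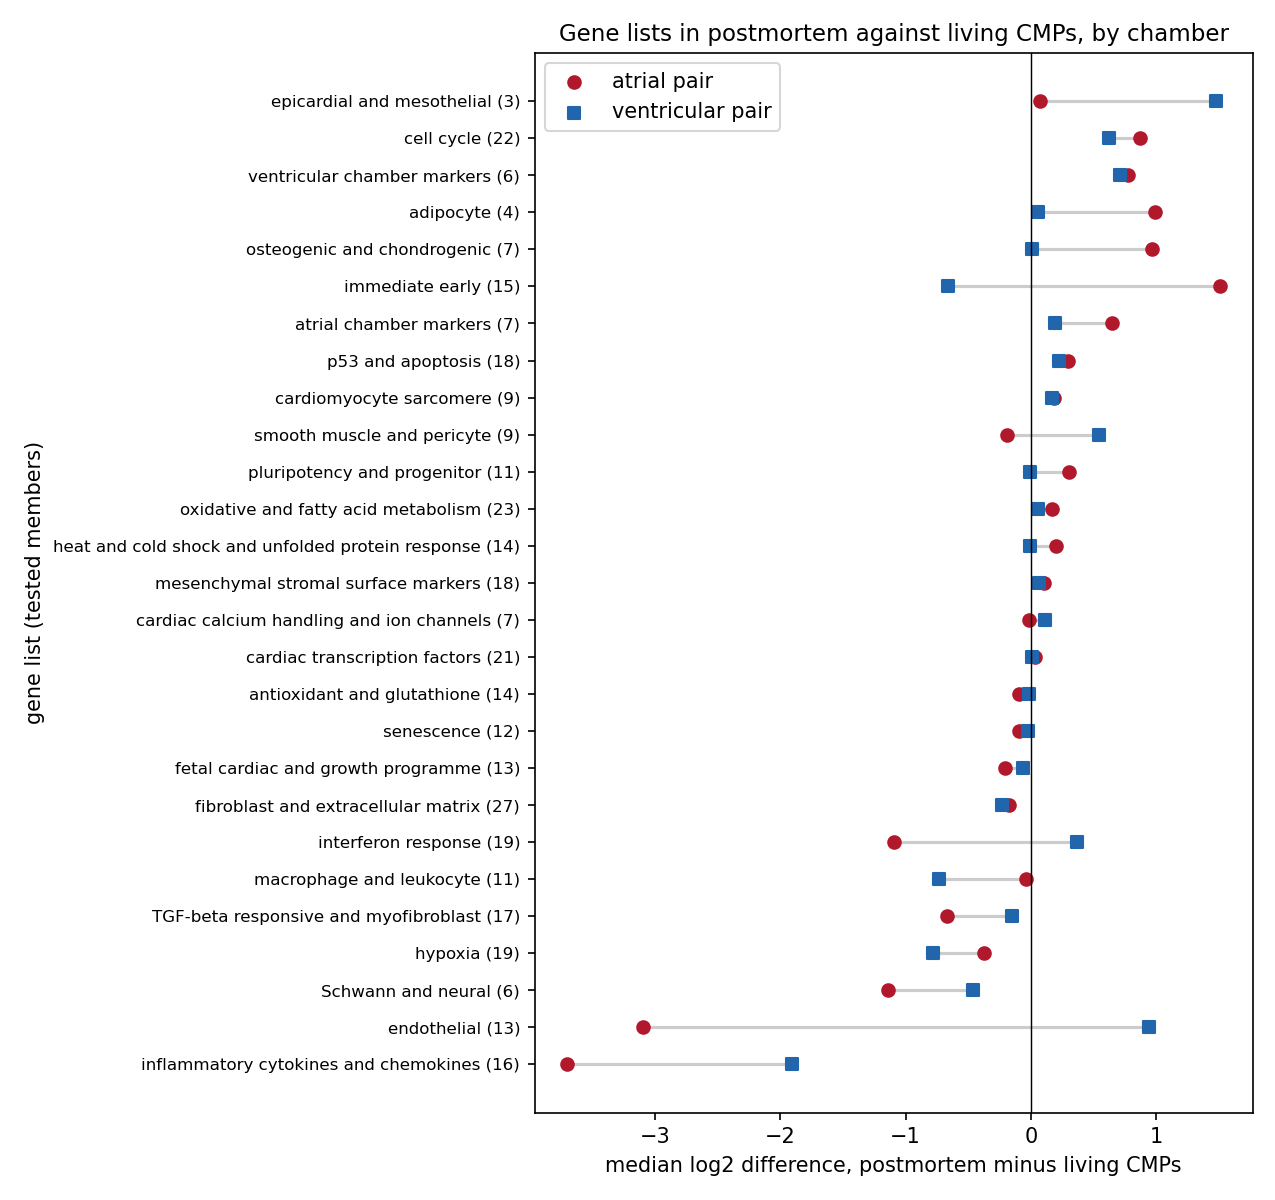
Median log2 difference between postmortem and living CMPs (x axis) for the tested members of each gene list (y axis, number of members in brackets), in the atrial pair (circles) and the ventricular pair (squares), with 1 array per side of each pair. Inflammatory genes lie at -3.70 and -1.90 and cell cycle genes at 0.87 and 0.62, while endothelial genes lie at -3.09 in the atrial and 0.94 in the ventricular pair.

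The postmortem difference was also taken within each chamber, with 1 array per side. Cxcl5 and Lcn2 were lower in both pairs, and by more in the atrial pair: Cxcl5 differed by -10.22 there and by -2.03 in the ventricular pair, and Lcn2 by -6.32 and -2.52. The cardiac transcription factors Gata4 (-2.31 and 0.35), Nkx2-5 (-2.20 and 0.57) and Tbx20 (-2.82 and 0.50) and the endothelial gene Esam (-3.61 and 1.27) lay apart in sign. Fos was higher in the atrial pair alone (3.57 and -1.21). The interaction test called 440 of 19011 genes, 296 with the higher difference in the ventricular pair and 144 in the atrial pair. Across those 19011 genes, which are not independent replicates, the atrial and ventricular differences had a Pearson's r of 0.397 and a Spearman's rho of 0.384, and 63.5% of genes had the same sign. Both pairs were at least 2-fold apart in the same direction for 570 genes, 247 higher and 323 lower, and in opposite directions for 109. Only 5 genes passed the interaction test after quantile normalization. Its spread came from the fetal pair alone, so a dependence on chamber cannot be told apart from a deviation of the postmortem atrial array.

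The chamber of origin was compared within CMPs over both source states. Rgs5, a regulator of G-protein signalling found in pericytes, fell by 6.49 ± 0.38 from atrial to ventricular CMPs (adjusted p = 0.0453, 2 arrays against 2), and Pgm5, a phosphoglucomutase-related protein of cell adhesions, fell by 4.42 ± 0.24 (adjusted p = 0.0453). Both were well above background on both atrial arrays and on 1 ventricular array, and the other 2 Pgm5 probes differed by -3.84 and -2.69. They were the 2 calls among 18910 genes tested, with 1557 at an unadjusted p under 0.05. The Rgs5 probe lies at 171623021 to 171623080 of chromosome 1 and the Pgm5 probe at 24757846 to 24757905 of chromosome 19 (mm9). Patterning genes had large differences of group means that did not pass: Hoxa3 was at least 35.4-fold lower in ventricular CMPs (adjusted p = 0.178), Irx1 at least 22.6-fold (adjusted p = 0.196) and Hoxa2 at least 8.13-fold (adjusted p = 0.438). These bounds rest mostly on the postmortem atrial array, with log2 signals of 2.69, 1.48 and 0.91 in this order. On the living atrial array the signals were -1.40, -1.49 and -3.87. Meox2 (4.94 ± 1.02) and Meox1 (4.12 ± 0.61), homeobox genes of mesoderm, and Eya2 (4.03 ± 0.70), all 3 dim on the postmortem atrial array, stood higher in ventricular CMPs with adjusted p-values of 0.164 to 0.284. So did the chemokine Ccl8 (3.60 ± 0.48) and the matricellular gene Postn (3.05 ± 0.47), while Penk (-6.38 ± 1.00, dim on 1 ventricular array) and the mesothelial Gpm6a (at least 9.61-fold, adjusted p = 0.107) stood lower. In limma neither call held after quantile normalization (1536 genes at an unadjusted p under 0.05), with the deposited series table (1557) or with the mean of probes (1535). Nor did they hold with no trend (1525), a robust prior (1515), the CMP arrays alone (1573), no source-state term (955) or without either fetal array. The stricter filter (1240) left both genes untested, since each is dim on the living ventricular array. Without postmortem atrial, postmortem ventricular, living atrial or living ventricular CMPs there were 395, 407, 1721 and 1458 calls, both genes among them.

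Interferon-response genes stood higher in ventricular CMPs for 18 of 19 members (median 0.96, camera adjusted p = 6.93e-07), with Cxcl10 at 2.63 ± 0.58 and Oas1a at 2.26 ± 0.56. Hypoxia-responsive genes were higher for 16 of 19 (median 0.61, adjusted p = 1.69e-05), with Ddit4 at 1.80 ± 0.30, Vegfa at 1.40 ± 0.17 and, against the list, Ndrg1 at -2.33 ± 0.37. Cell cycle genes were higher for 21 of 22 (median 0.30, adjusted p = 1.62e-04), among them Rrm2 (0.87 ± 0.20), and inflammatory genes for 11 of 15 (median 1.38, adjusted p = 0.0151), led by Cxcl5 (4.45 ± 1.75). Immediate early genes were lower for 11 of 15 (median -0.70, adjusted p = 0.00428), with Fos at -2.37 ± 1.04, and all 6 atrial chamber markers were lower (median -0.50, adjusted p = 0.0151), led by the Wnt modulator Dkk3 (-2.07 ± 0.41). For these 6 lists the adjusted p = 0.79 to 0.855 with an estimated correlation. In limma no member passed over all genes. Adjusted over the list alone, 6 hypoxia genes and 1 atrial marker passed, and from 1 to 9 members of each list had an unadjusted p under 0.05. Without either postmortem array the immediate early median was 0.08, and the interferon (median 0.24) and inflammatory lists (median 0.19) did not pass. The inflammatory list did not pass with the stricter filter (median 0.67), the CMP arrays alone or without either fetal array either, and Cxcl5 ranged from 0.35 to 8.55. Without either living array the cell cycle (median 0.19) and hypoxia lists (median 0.36) did not pass, nor did the atrial markers without the living ventricular array (median -0.36) or with no filter on dim probes (median -0.16).

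The fetal and adult hearts were the positive controls of the series and show what CMPs share with heart tissue. Contractile genes were lower in CMPs, though 7 to 10 of the 24 sarcomere genes were well above background on each CMP array. Among them were Tnnt2, Tnni1, Ldb3 and Ankrd1, each on all 4, as was Acta1, which lies outside that list. Against fetal heart, cardiac actin Actc1 was at least 16918-fold lower (adjusted p = 2.43e-05, 4 arrays against 2) and the myosin light chain Myl3 at least 16154-fold lower, while Myh7, well above background on 1 of 4 CMP arrays, fell by 14.12 ± 0.33. All 24 sarcomere genes were called lower (24 adjusted over the list alone), with a median of -10.79, or -10.09 with 13 genes at their bounds (camera adjusted p = 1.21e-16, adjusted p = 0.344 with an estimated correlation). For Myh6 the main probe was not well above background on any CMP array, whereas another probe was on 1, and the 2 probes differed by -13.96 and -7.16. Blood transcripts were lower too: Hbb-b1 was at least 14615-fold and Hbb-y at least 13358-fold lower, Hba-a1 (well above background on 1 of 4 CMP arrays) fell by 14.57 ± 0.28, and all 9 erythroid genes were called (median -12.80, or -10.88 with 6 at their bounds). The sizes of the Myh7 and Hba-a1 falls rest mostly on dim CMP values. Altogether 9555 of 20052 genes passed, 4478 higher and 5077 lower in CMPs, while with the stricter filter 4114 were higher and 3486 lower.

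Stromal genes stood higher in CMPs than in fetal heart. Mmp3, the stromelysin-1 gene, was at least 3321-fold higher, Wisp2 at least 2526-fold and the protease inhibitor Serpina3n at least 1542-fold, and Sod3, the extracellular superoxide dismutase, rose by 10.22 ± 0.25. Of 18 mesenchymal surface markers, 13 rose and 2 fell (median 1.60, camera adjusted p = 4.51e-04, adjusted p = 0.344 with an estimated correlation), with Ly6a (Sca-1) at 9.43 ± 0.37, Thy1 at 6.81 ± 0.27 and Vcam1 at 3.44 ± 0.19. Of 27 extracellular matrix and fibroblast genes, 21 rose and none fell (median 1.86, adjusted p = 2.19e-08, 0.328 with an estimated correlation). S100a4 rose by 8.75 ± 0.20, Timp1 by 5.24 ± 0.21, Lox by 4.87 ± 0.37, Fbln2 by 4.17 ± 0.18 and Col1a1 by 0.79 ± 0.16, though Col1a1 did not pass with a CMP array left out or with the 2-fold minimum (5 of 16 other settings). All 12 inflammatory genes rose (median 6.07, or 5.65 with 4 at their bounds, adjusted p = 4.46e-07), with Cxcl5 at least 861-fold and Cxcl1 at least 330-fold higher. All 19 interferon-response genes rose as well (median 4.49, or 4.45 with 5 at their bounds, adjusted p = 8.77e-10), with Ifit3 at 8.43 ± 0.35, Isg15 at 6.56 ± 0.44 and Ifit1 at least 146-fold. With an estimated correlation these 2 lists had an adjusted p = 0.328 and an adjusted p = 0.344. Adjusted over the list alone the counts of these 4 lists were the same.

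Cardiac regulators were only partly retained. Gata4 was at 2.73 in CMPs and 3.27 in fetal heart (log2 signal relative to the 75th percentile), a difference of -0.54 ± 0.56 that did not pass (adjusted p = 0.474) and was 0.13 without the postmortem atrial or the living ventricular array. Nkx2-5 fell by 6.44 ± 0.64 and Hopx by 6.75 ± 0.66. Of 25 cardiac transcription factors, 15 fell and 1 rose (median -1.91, camera adjusted p = 5.87e-04), as did 13 and 1 of 18 calcium-handling and channel genes (median -4.73, or -3.87 with 7 at their bounds, adjusted p = 2.71e-04), 12 and 1 of 15 atrial markers (median -4.61, or -4.08 with 7 at their bounds, adjusted p = 2.89e-05) and 11 and 0 of 12 ventricular markers (median -5.47, adjusted p = 2.14e-06). Of the fetal growth programme 17 of 18 genes fell (median -7.11, adjusted p = 8.77e-10), with Igf2 at least 216-fold lower, and 22 of 27 oxidative metabolism genes fell (median -1.69, adjusted p = 6.16e-08), with the heart isoform Cox6a2 at -9.47 ± 0.36. With an estimated correlation these 6 lists had an adjusted p = 0.328 to an adjusted p = 0.469. The fetal growth list also had a median of -5.49 for adult against fetal heart, or -5.29 with 5 genes at their bounds. For CMPs against adult heart its median was -0.91. Its fall against fetal heart can therefore not be told apart from the age of the source tissue. Markers of other cell types were lower: 11 of 12 epicardial and mesothelial genes (median -5.88, or -5.48 with 3 at their bounds, adjusted p = 1.59e-05), with Wt1 at least 184-fold and Krt8 at least 161-fold, 12 of 15 endothelial genes (median -2.91, adjusted p = 6.7e-04), with Vwf at -4.91 ± 0.92 and Pecam1 at -2.03 ± 0.43, 10 of 16 leukocyte genes (median -2.54, adjusted p = 0.00624), with Tyrobp at -5.26 ± 0.61, and 6 of 12 smooth muscle and pericyte genes (median -1.41, adjusted p = 0.0115). The other Vwf probe differed by -3.68. Adjusted over the list alone 2 atrial markers and 3 leukocyte genes rose, in place of 1 and 2, and the other counts of this paragraph were the same. With the stricter filter, which leaves out genes dim on any array, the calcium-handling (median 0.17), atrial (-0.33), ventricular (-5.65), epicardial (-4.29), leukocyte (-1.42) and smooth muscle lists (-0.91) did not pass, and without either fetal array Vwf and Pecam1 did not. With an estimated correlation these 4 lists and the erythroid list had an adjusted p = 0.344 to an adjusted p = 0.506.

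Growth and stress lists divided. Cell cycle genes fell for 21 of 22 members against fetal heart (median -2.08, adjusted p = 3.92e-10), with Mcm5 at -2.58 ± 0.22 and Mki67 at -1.74 ± 0.16. The p53 and apoptosis list rose for 15 of 18 genes (median 1.62, adjusted p = 1.38e-05), with Cdkn1a at 3.76 ± 0.20, and the senescence list for 7 of 12 (median 2.64, adjusted p = 0.041), with the main Cdkn2a probe at least 838-fold higher. TGF-beta responsive (median 1.65, adjusted p = 0.00567), immediate early (median 1.98, adjusted p = 0.00828) and antioxidant genes (median 1.33, adjusted p = 0.00828) each rose for 9 members. Adjusted over the list alone 10 TGF-beta responsive genes rose and 2 p53 and 4 senescence genes fell, in place of 9, 1 and 3, and the other counts were the same. With the stricter filter the senescence (median -0.02) and immediate early lists (1.52) did not pass. With an estimated correlation these 6 lists had an adjusted p = 0.344 to an adjusted p = 0.555. Of 11 tested pluripotency and progenitor genes, Klf4 rose (2.69 ± 0.21) and 4 fell, among them Kit (-3.01 ± 0.89, not called without either fetal array or without a trend), Utf1 (-2.50 ± 0.43) and Nes (-2.28 ± 0.14), with no shift of the list (median -0.33, adjusted p = 0.466). Hypoxia genes (median 0.24, adjusted p = 0.316), stress-protein genes (median 0.47, adjusted p = 0.129), bone and cartilage genes (median 1.55, adjusted p = 0.223), Schwann and neural genes (median -1.07, adjusted p = 0.293), fat cell genes (median 0.84, adjusted p = 0.646) and the 3 sex-linked genes (median -7.00, or -4.95 with 1 at its bound, adjusted p = 0.233) did not shift as lists.

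**Figure D2:**
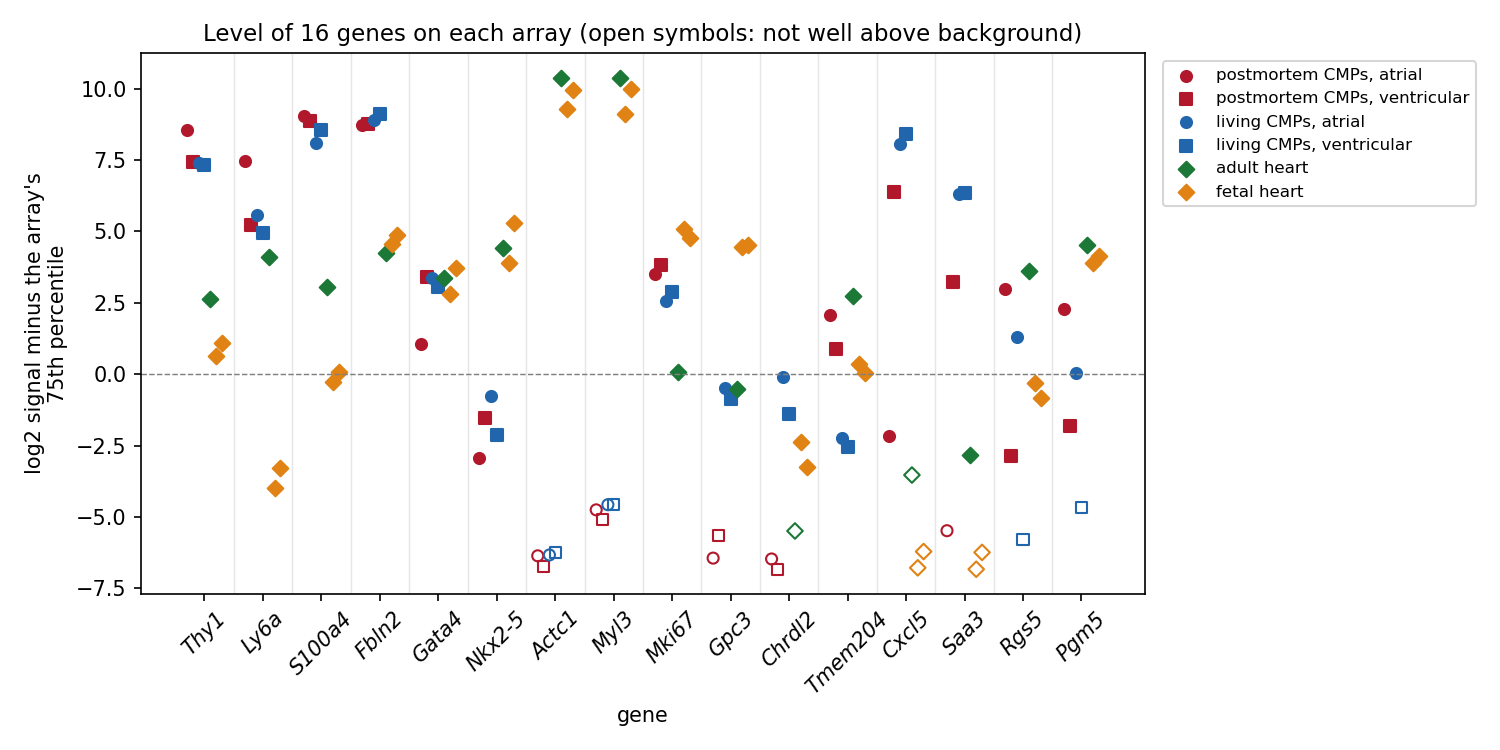
Log2 signal relative to each array's 75th percentile (y axis) for 16 genes (x axis) on each of the 7 arrays, with 1 symbol per array, shaped and coloured by source and drawn open where the probe was not well above background. Actc1 and Myl3 are open on all 4 CMP arrays, Gpc3 and Chrdl2 are open on both postmortem CMP arrays, and Cxcl5 is lowest among CMPs on the postmortem atrial array.

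Against adult heart, contractile transcripts were likewise lower in CMPs. Actc1 was at least 28964-fold lower (adjusted p = 7.66e-05, 4 arrays against 1), Myl3 at least 28914-fold, myoglobin (Mb) at least 18090-fold and the mitochondrial creatine kinase Ckmt2 at least 11089-fold, and 23 of 24 sarcomere genes were called lower (median -13.74, or -11.81 with 13 at their bounds, camera adjusted p = 1.46e-15). All 27 oxidative and fatty acid metabolism genes fell (median -3.73, adjusted p = 1.19e-12), with Cox6a2 at -12.40 ± 0.47 and Cpt1b at least 1022-fold lower. The secreted genes Il6 (at least 122-fold), Cxcl5 (at least 416-fold, not called without either fetal array), Col2a1 (at least 99.8-fold) and Lox (at least 211-fold) stood higher in CMPs, as did the glutamate transporter Slc1a6 (at least 270-fold). Altogether 9878 of 20278 genes passed, 4731 higher and 5147 lower. With quantile normalization, the series table or the stricter filter more were higher than lower, so the larger side depends on the processing. The Cpt1b bound is that of its main probe, and the other probe differed by -8.88. The adult group is 1 array, assumed to vary like the other groups.

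Proliferation genes stood higher in CMPs than in adult heart, with 20 of 22 called (21 adjusted over the list alone, median 3.61, or 3.49 with 4 at their bounds, camera adjusted p = 4.46e-12). Ccnb1 rose by 5.65 ± 0.21, Plk1 by 4.92 ± 0.19 and Mki67 by 3.12 ± 0.21. Matrix genes rose for 22 of 27 members (23 adjusted over the list alone, median 2.75, adjusted p = 5.36e-09), with S100a4 at 5.57 ± 0.26, Fn1 at 4.74 ± 0.28 and Col1a1 at 2.72 ± 0.21, and mesenchymal surface markers for 11 of 18 (12 adjusted over the list alone, median 2.00, adjusted p = 0.00137), with Thy1 at 5.03 ± 0.35. The main Cd44 probe rose by 5.41 ± 0.31, and the other 2 Cd44 probes differed by 0.95 and 3.00. For Vwf, given below from its main probe, the other probe differed by -2.89. Inflammatory genes rose for 9 of 15 members (11 adjusted over the list alone, median 3.1, adjusted p = 0.00669) and interferon-response genes for 8 of 19 (median 1.54, adjusted p = 0.00137). Leukocyte genes fell for 14 of 16 members (median -4.82, adjusted p = 5.48e-06), with Tyrobp at -7.09 ± 0.78 and C1qa at -8.18 ± 1.12, endothelial genes for 10 of 15 (12 adjusted over the list alone, median -3.56, adjusted p = 7.46e-04), with Vwf at -6.46 ± 1.18, and fat cell genes for 6 of 8 (median -4.20, or -3.80 with 3 at their bounds, adjusted p = 0.00304), with Fabp4 at -4.78 ± 0.42 and Lpl at -5.05 ± 0.51. Nkx2-5 fell by 6.25 ± 0.83, while Gata4 (-0.64 ± 0.72, adjusted p = 0.493) did not pass and was 0.03 without the postmortem atrial or the living ventricular array. Of 29 lists 20 passed camera, and with an estimated correlation all 20 had an adjusted p = 0.354 or more. The hypoxia list had a median of -0.38 and a mean of 0.31 (adjusted p = 0.9).

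Adult and fetal heart differed in maturation genes. The embryonic globins Hbb-y and Hba-x were not above background on the adult array, at least 7656-fold and at least 1080-fold lower than in fetal heart (adjusted p = 3.55e-04 for both, 1 array against 2). Slow skeletal troponin Tnni1 fell by 8.80 ± 0.71, and the fetal growth genes Dlk1 (main probe at least 1183-fold), Igf2bp1 (at least 39.6-fold) and Igf2bp3 (at least 38.8-fold) were lower. The other Dlk1 probe differed by -9.10. All 22 cell cycle genes fell (median -5.55, or -5.48 with 4 at their bounds, camera adjusted p = 4e-19), with Mki67 at -4.86 ± 0.23 and Top2a at least 92.5-fold lower. Oxidative metabolism genes rose for 22 of 27 members (25 adjusted over the list alone, median 2.29, adjusted p = 4.76e-08), with Ckmt2 at 8.66 ± 0.64 and the fatty acid transporter Cd36 at 3.65 ± 0.59. Myom2 (6.53 ± 0.40) and Myh6 (1.46 ± 0.37, the other probe 4.36, not called without wild-type fetal heart, without a trend or with quantile normalization) were higher in adult heart. Leukocyte genes rose for 9 of 16 members (10 adjusted over the list alone, median 1.93, adjusted p = 1.36e-04), with Lyz2 at 4.52 ± 0.35, and fat cell genes for 6 of 8 (7 adjusted over the list alone, median 3.77, or 2.87 with 3 at their bounds, adjusted p = 0.00141), with Adipoq at least 6.33-fold. The largest rises included Aqp6 (at least 633-fold), Amy2a5 (at least 548-fold), Scgb1c1 (at least 519-fold), Try5 (at least 394-fold), Tuba8 (10.73 ± 0.47) and Rpl3l (10.38 ± 0.92). Altogether 7610 of 20946 genes passed, 4014 higher and 3596 lower in adult heart, against a median of all genes of 0.12. With quantile normalization or without wild-type fetal heart more were lower than higher. With an estimated correlation all 13 lists that passed had an adjusted p = 0.526 or more.

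**Figure D3:**
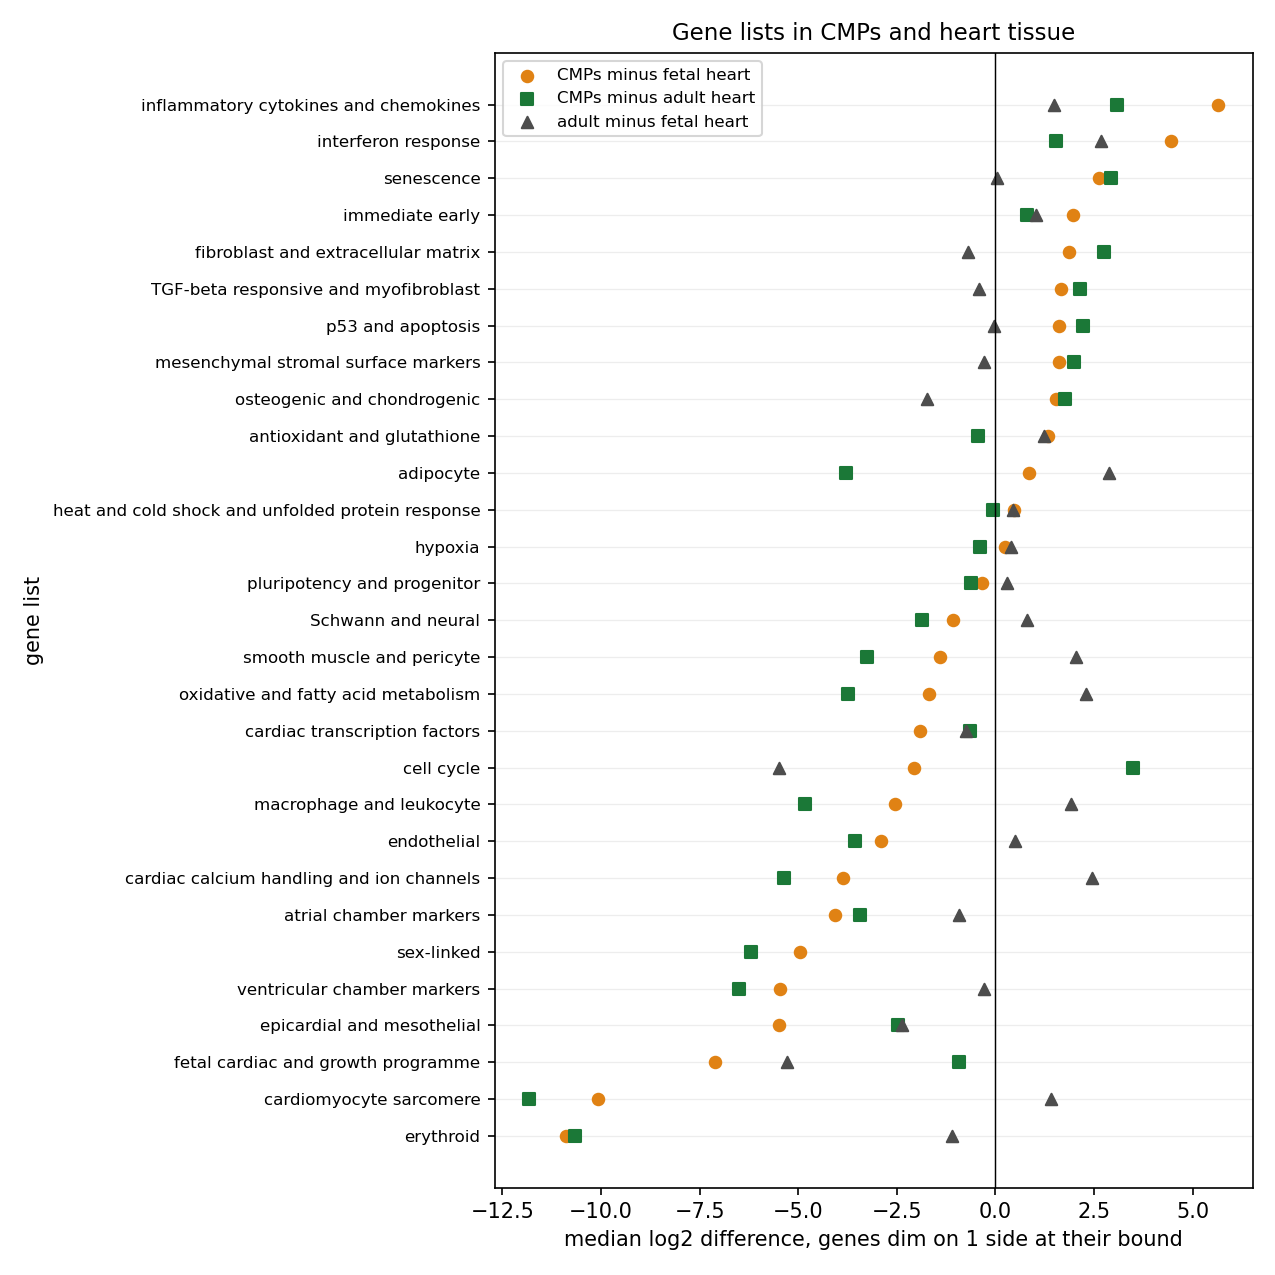
Median log2 difference (x axis) of each gene list (y axis), with genes not well above background on 1 side placed at their bound, for CMPs minus fetal heart (circles), CMPs minus adult heart (squares) and adult minus fetal heart (triangles). Sarcomere genes lie at -10.09 and -11.81 for CMPs against fetal and adult heart, and cell cycle genes at -2.08 and 3.49.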

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

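The interaction test was planned, and the genes given are those of the rule for named genes. The interaction test of the postmortem difference with chamber called 440 genes. Among named genes, the ventricular minus the atrial difference was 8.68 for Saa3, 8.20 for Cxcl5, 5.36 for Comp, 4.88 for Esam, 3.80 for Lcn2, 3.71 for Cxcl1, 3.34 for Egfl7, 3.32 for Tbx20, 3.03 for Fabp7, 3.02 for Tcf21, 2.77 for Nkx2-5 and 2.66 for Gata4. It was -2.01 for Dusp1, -4.26 for Penk, -4.78 for Fos and -5.66 for Dlk1. The sizes for Saa3, Fabp7, Penk and Dlk1 rest on at least 1 dim CMP array and are set in part by the floor. Each side of each pair is a single array, the postmortem atrial array stood apart from the other CMPs, and the spread of this test came from the fetal pair alone. The fit gave infinite prior degrees of freedom, so each gene took the spread of the trend and not its own. With a simulated spread as in the fit of all arrays, the test recovered 0% of changed genes and made 1 call, a false one. That simulation does not say how many of the 440 calls are false. No spread between CMP cultures of the same source entered the test, so these calls do not show that the chambers differ. Quantile normalization left 5 genes.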

How the results depend on the processing

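All alternatives were planned before the data were examined, and the cause of a change was not tested unless it is stated. For postmortem against living CMPs, 20 calls became 53 with normexp, 62 with no filter on dim probes (more genes tested), 10 with the mean of probes, and 0 with no trend, with the 4 CMP arrays alone or with no chamber term. Leaving out an array gave 0 to 1695 calls. For ventricular against atrial CMPs, 2 calls became 25 with normexp, 41 with no filter, and 0 after quantile normalization, with the series table, the stricter filter, the mean of probes, no trend, a robust prior, the CMP arrays alone or no source-state term, and 0 to 1721 with an array left out. In limma the counts of 0 came with 955 to 2221 genes at an unadjusted p under 0.05. A CMP array left out leaves only the fetal pair to estimate the spread, and its lone partner is assumed to vary alike. The interaction count fell from 440 to 5 with quantile normalization. Genes 2-fold apart in both chambers numbered 570, but 235 with normexp and 324 with the stricter filter, and the correlation of 0.397 was 0.147 with no filter, 0.349 with the stricter filter and 0.368 with the mean of probes. Shifted lists numbered 8 for postmortem against living CMPs, but 5 with quantile normalization, the series table or the mean of probes, 3 with the CMP arrays alone and 3 to 12 with an array left out. They numbered 6 for the chambers, but 12 with no filter and 5 to 11 with an array left out, and 22 against fetal heart, but 13 with the stricter filter. With an estimated correlation, a setting that hardly any list could pass here, 0 lists passed in any comparison. The cell cycle and inflammatory lists held in all 13 other settings for postmortem against living CMPs, with medians of 0.62 to 0.87 and -3.70 to -1.55. Settings without a CMP array repeat the differences of the atrial or the ventricular pair and are not separate checks.

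Signs turned when 1 CMP array was left out. With either atrial array left out, the postmortem difference of a gene is that of the ventricular pair. With either ventricular array left out, it is that of the atrial pair. The chamber difference without either postmortem array is likewise that of the living pair, so these settings are not separate checks. Without the postmortem atrial or the living atrial array, the postmortem difference had the opposite sign, so that over all arrays left out it ranged from -0.66 (or -0.65) to 1.51 for the immediate early list, -1.10 to 0.37 for the interferon list, -2.31 to 0.35 for Gata4, -2.20 to 0.57 for Nkx2-5, -1.42 to 0.52 for Pecam1, -1.21 to 3.57 for Fos, -2.82 to 0.50 for Tbx20, -3.01 to 0.0112 for Tcf21, -3.09 to 0.243 for Egfl7 and -3.61 to 1.27 for Esam. Without either postmortem array the chamber difference turned, with ranges of -1.46 to 0.0813 for the immediate early list and -4.75 to 0.0244 for Fos. Gata4 turned without the postmortem atrial or living ventricular array, with ranges of -1.20 to 0.127 against fetal and -1.30 to 0.0259 against adult heart. Both of these settings give the same CMP mean, which then rests on the living atrial and postmortem ventricular arrays alone. Over all named genes, 2367 values under an alternative kept their sign and side of the threshold, 159 newly passed, 80 no longer passed and 22 turned, and for lists these were 761, 0, 139 and 9. The stricter filter turned 3 list medians, to 0.13 (Schwann and neural, postmortem against living), and 0.166 (calcium handling) and -0.0187 (senescence) against fetal heart, with fewer genes tested. Every other count of genes or lists stayed within 1.5 times the main one. The median of all genes for adult against fetal heart, 0.12, was 0.18 with normexp, 0.01 with quantile normalization, 0.21 with the mean of probes and 0.53 with no filter. For CMPs against adult heart it was -0.05, but -0.11 with normexp, -0.15 with the mean of probes and -0.50 with no filter. The test could not be run with a slide as a block, with 1 slide, nor could the interaction and the paired values be computed with an array left out. No paired analysis was possible because the labels link no arrays by animal, culture or replicate number. Chamber, which both source states share, is a term of the fit.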

Other observations

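The tests on shared probe sequence, on leukocytes and on the ventricular pair were chosen after the results they address had been seen, while those on local background and on pancreatic genes were chosen before. The levels that open this part were looked up after the comparisons had been seen. Leukocyte transcripts were present in CMPs at uneven levels. Itgam stood at 5.17 to 5.75 on the 4 CMP arrays and at 5.22 in adult heart (log2 signal relative to the 75th percentile), while Ptprc was well above background on 1 CMP array, living ventricular. Csf1r stood at 1.34 to 2.01 in CMPs and at 5.18 in adult heart. Of the 16 macrophage and leukocyte genes, 11 were well above background on both living arrays.

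Sex-linked transcripts differed between CMPs and hearts, with exceptions on both sides. Xist was well above background on all 4 CMP arrays and 2.11 ± 0.54 higher than in fetal heart (adjusted p = 0.0241), where it was above background on 1 of 2 arrays, but was not called without the transgenic fetal array. The Y-linked Ddx3y was well above background on no CMP array and Eif2s3y on the postmortem ventricular array alone, and wild-type fetal heart carried Xist and both Y-linked genes. On the adult array Xist was dim (log2 signal -5.74), while Ddx3y (1.77) and Eif2s3y (2.66) were well above background. The transgenic fetal array likewise had dim Xist (-4.65) with Ddx3y (0.11) and Eif2s3y (1.31) above background. For these genes, the sex of the source animals cannot be told apart from a difference between CMPs and heart. Ddx3y was at least 30.9-fold lower than in fetal heart (adjusted p = 1.94e-04).

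The 19 probes called lower in postmortem CMPs are mostly bright probes without a gene symbol that moved by about the same amount. With normexp on the raw signals their median was -2.41 in place of -2.52. Apart from Gpc3 and Chrdl2, their mean living signals lay 4.86 to 9.33 log2 units above the 75th percentile. That percentile was 353 and 404 units on the living arrays, while the median local background was 23 to 39 units on the CMP arrays. Its subtraction could therefore hardly move these probes, and the test does not decide on effects of the slide position. Repeated sequences counted several times are a candidate explanation: 12 of the 19 shared a stretch of at least 20 bases with another called lower probe, against at most 2 in 1000 random draws of as many tested probes. The 12 fell into 4 groups with no such stretch in common between groups, and 7 probes shared none, so a single family was not shown. The call of 19 lower genes may therefore hold fewer separate transcripts, and Gpc3, Chrdl2, Emb, Wdr92 and Pip5k1a were not among those sharing a stretch. The Wdr92 and Pip5k1a calls rest on their main probes alone, since the other Wdr92 probe differed by -0.10. The other 2 Pip5k1a probes differed by -0.43 to 0.09. The source state of the tissue stays open as a biological cause of the shift itself, and was not tested apart from the position on the slide.

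Inflammatory cytokine and chemokine genes were lower in postmortem CMPs. Leukocytes in the living atrial culture are argued against, since in that pair the macrophage and leukocyte list had a median of -0.0380 (6 of 11 members lower, median absolute deviation 0.37) against -3.70 for the inflammatory list. In the ventricular pair they cannot be told apart: the median was -0.73, with 10 of 11 members lower, and Ptprc, C1qa and C1qc were well above background on the living array alone. The postmortem atrial array alone is argued against as well, since in the ventricular pair all 16 members were lower, with a median of -1.90 and a median absolute deviation of 0.82. Local background could not be told apart for part of the size: with normexp the list median was -1.55, 52.6% of the main value, while 12 of 16 members kept over 80% of their difference and Csf3, Lif and Cxcl2 shrank by the largest shares. A lower inflammatory state of cultures from stored tissue may remain as a hypothesis, with 1 array per chamber and source state.

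Pancreatic digestive enzyme transcripts were high on the adult heart array, where Amy2a5 and Try5 were among the largest rises over fetal heart. Pancreatic RNA in the commercial heart RNA may be a source, from a list of other acinar genes written before they were looked up. Of 27 on the array, 12 were well above background on the adult array and on neither fetal array, against 2.78% of all genes, and 24 were above background on the adult array. The highest levels on it were Try4 (3.84), Ctrb1 (3.43) and Sycn (2.38). Since 13 of the 27 were above background on a fetal array, the test stayed short of its mark of over 50%, and no biological explanation was tested.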
